A study of Mus musculus with 2 samples.

How the data were processed

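Gene expression was measured in B cells sorted from mouse spleen on 2 single-channel Affymetrix arrays, 1 of follicular B cells and 1 of marginal zone B cells. Per the labels' protocols, B cells of 3 female C57BL/6 mice were enriched with magnetic beads against B220 and stained for CD21 and CD23. Cells with high CD23 and intermediate CD21 were sorted as follicular, and cells with intermediate CD23 and high CD21 as marginal zone. Sorted cells were pooled before lysis, and about 100 ng of total RNA was amplified and biotin-labelled with the manufacturer's 2-cycle protocol. The labels do not say whether both populations came from the same mice.

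The deposited table holds 1 intensity per probe set and array, on a linear scale. Per the submitters' processing notes these intensities are MAS5 signals, which combine perfect-match and mismatch probes of a probe set into 1 value; the MAS5 version, the scaling target and detection calls are not given in the sources used here. The deposited intensities ran from 0.1 to 8520.6 for follicular and from 0 to 8203.3 for marginal zone B cells, over 22626 probe sets. Medians were 12.8 and 12.6, and the 2% trimmed means were 51.3 and 52.4, so the deposited arrays were already on nearly the same scale. The table held 0 probe sets named as AFFX controls, so the planned comparison of array controls, which would have covered RNA and labelling quality, was not made.

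Each array was scaled to the same 2% trimmed mean, by factors of 1.01 for follicular and 0.990 for marginal zone B cells. A floor was set at the median of all scaled values of both arrays, a signal of 12.7, and lower values were raised to it, since MAS5 signals near the background have no reliable order. A probe set counted as measured when its higher value exceeded the floor, which 12847 probe sets did. Probe sets were named from the platform's annotation table: 20380 had 1 gene, 691 had several and 1555 were not listed there. The Entrez identifiers of 20351 of the 20380 were found in the RefSeq gene table of GRCm38.p6, and 0 symbols needed an update. No coordinates are given, since no genome build is named for the deposited values. Each gene took its measured probe set with the highest mean log2 value, which gave 7695 genes. Where one array was below the floor, the fold is written "at least" and is relative to the floor. A fold with no such words is a ratio of 2 scaled signals.

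With 1 array per group there is no replicate error, no test between the populations can be made, and no p-value is given. Differences are described by size, with 2-fold as the threshold. The nearest thing to a repeat measurement is the agreement of different probe sets of 1 gene on the same arrays. It covers probe behaviour only, not variation between mice, sorts or labellings. The number of arrays limits the precision of every value.

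Fixed before the data were examined were 33 gene lists, chosen from general knowledge: genes reported for each population, B cell pathways, metabolism, and markers of other cells that a B220-enriched sort could hold. For each list the median log2 ratio of marginal zone over follicular signal was set against 10000 random lists of the same size, matched on mean log2 value in 20 bins. The percentile describes these 2 arrays only. About 1.65 of 33 lists would lie outside the middle 95% by chance if their genes varied independently. The genes named are the 15 highest and 15 lowest of the genes with a signal of at least 45.7 (the 75th percentile) on one array and with all measured probe sets of 1 sign, together with up to 4 members of each list with the largest absolute log2 ratio. Unnamed gene models and antigen receptor variable segments were passed over, which left out Ighv14-2 and no other gene. A gene named outside this rule is marked as chosen after its values were seen.

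The procedure was tested on simulated data: a pair of arrays was drawn from the mean signal of each probe set and the robust spread of the observed log2 ratios at that signal, as normal deviates, with 200 genes changed. The changed genes were drawn only from genes with a signal of at least 45.7 on one array, so recovery of dimmer genes was not simulated. Of 50 such genes changed 2-fold, 56% passed the 2-fold threshold, as did 92% of 50 changed 4-fold and 100% of 50 changed 8-fold. Of the 7799 unchanged genes, 7.64% passed it and 0.269% passed 4-fold. That spread was taken from the real pair, so it holds real differences as well as noise, and normal deviates leave out any heavier tails; the shares describe this simulation only. Of 100 random lists of 20 genes, 3 lay outside the middle 95%. Simulated genes varied independently, so this count does not check lists of genes that vary together. The alternatives were 4 other scalings, 2 other floors, no floor, a pseudocount of 12.7 in place of the floor, 2 other rules for probe sets, thresholds of 1.5-fold and 3-fold, unfloored ratios, and lists without the sort gate genes. Chosen after seeing the data were counts without the genes of other cells and the marginal zone list without genes set aside as expressed by macrophages. So were list medians over the probe sets not used otherwise, and 6 further gene lists. The analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.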

Results

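Follicular B cells, the recirculating majority of splenic B cells, were compared with marginal zone B cells, which reside next to the marginal sinus of the spleen and respond early to blood-borne antigens. The comparison asked how the transcriptomes of these mature B cell subsets differ. There was 1 array of each population, made from pooled sorted cells, so values carry no replicate error and differences are given as sizes. Signals are scaled MAS5 intensities, with follicular before marginal zone unless stated otherwise.

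The sort was visible in the transcripts of its own markers. Fcer2a, which encodes CD23, had a signal of 726.8 in follicular and 89.6 in marginal zone B cells, 8.11-fold higher in follicular cells. Cr2, which encodes CD21, went the other way, with signals of 277.9 and 889.9, 3.20-fold higher in marginal zone cells. Ptprc, the gene of the B220 antigen used for enrichment, was at 1901 and 1987, a log2 ratio of 0.063 that turned to -0.0058 after quantile normalization. These genes chose the cells, so they check the labels and are not a result of the comparison.

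Most genes had similar signals in both populations. Of 7695 measured genes, 6983 (90.7%) differed by less than 2-fold. There were 338 genes at least 2-fold higher in marginal zone and 374 at least 2-fold higher in follicular B cells, and at 4-fold the counts were 35 and 22. The log2 signals of the arrays correlated with Pearson's r = 0.943 and Spearman's rho = 0.889 across genes, which are not independent replicates. The SD between probe sets of 1 gene was 0.43 on the log2 scale, over 2622 genes with several measured probe sets. Of 240 genes past 2-fold with several probe sets, the mean of the other probe sets had the same sign in 203 (84.6%) and was itself past 2-fold in 72 (30.0%). Past 2-fold were 9.25% of genes, against 7.64% of unchanged genes in the simulation, and 0.741% against 0.269% were past 4-fold. Of genes with a signal of at least 45.7 on one array, 11.2% were past 2-fold, against 4.87% in the simulation. These genes were chosen by the higher of their 2 real signals, also for the simulation. That choice favours large ratios in the real pair only, so the gap between the 2 shares is partly built in. The simulated spread was fitted to this pair, so these shares are no error rate for single genes.

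**Figure D1:**
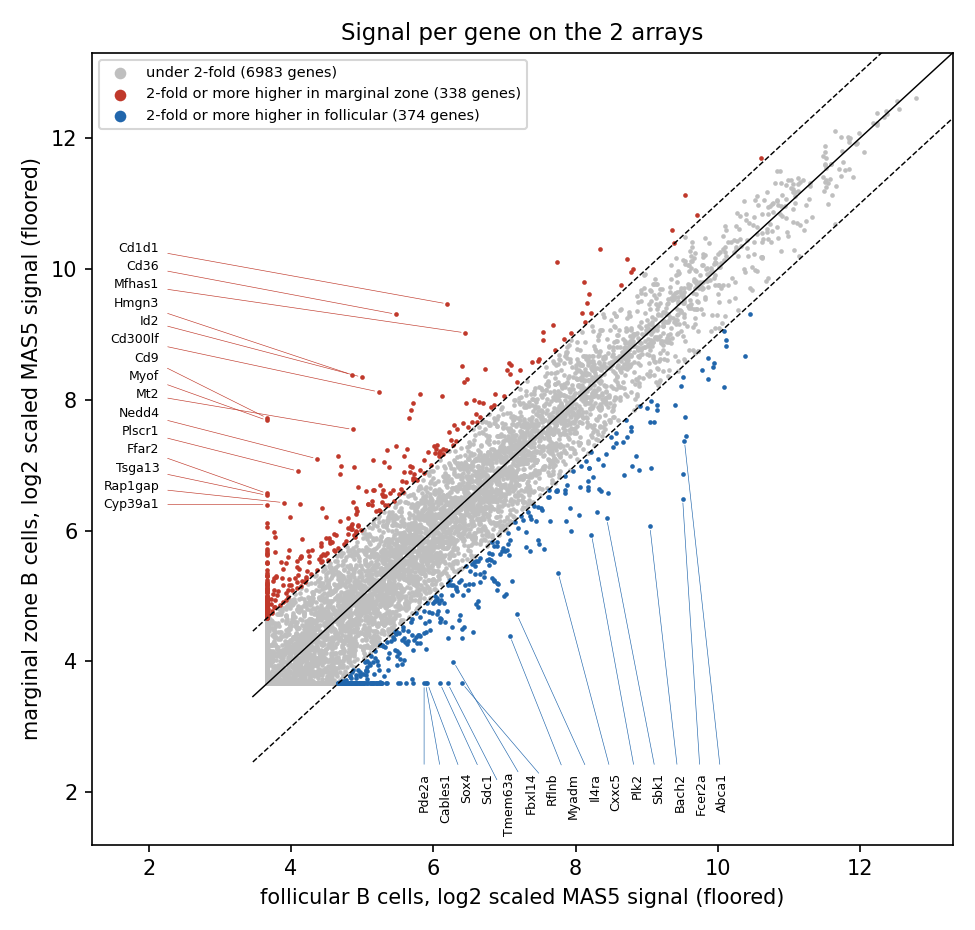
Scaled MAS5 signal of 7695 genes in follicular (horizontal axis) and marginal zone B cells (vertical axis), both as log2 with values under 12.7 raised to 12.7. Points are genes, the solid line marks equal signal and the dashed lines 2-fold differences; 338 genes (red) lie above and 374 (blue) below them, and the 15 highest and 15 lowest genes chosen by rule are named.

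The genes highest in marginal zone over follicular B cells included membrane proteins and nuclear factors. Cd9, a tetraspanin, was at 12.2 and 210.7, at least 16.6-fold higher in marginal zone cells, and Myof, a ferlin of membrane repair, was at least 16.2-fold higher. Cd36, a scavenger receptor for lipids, was at 44.5 and 633.5, 14.2-fold higher, with 3 probe sets between 3.26 and 3.83 on the log2 scale. Cd1d1, which presents lipid antigens to natural killer T cells, was at 73.4 and 706.7, 9.63-fold higher. Other membrane proteins in this group were Cd300lf (7.40-fold), the phospholipid scramblase Plscr1 (7.04-fold) and Ffar2, a receptor for short-chain fatty acids (at least 7.48-fold). The other probe set of Ffar2 was at only 1.02 on the log2 scale. Among nuclear factors, the chromatin protein Hmgn3 was 11.5-fold and Id2, an inhibitor of E proteins, 10.2-fold higher. The 3 probe sets of Id2 ran from 0.66 to 3.35 on the log2 scale. The remaining genes were Tsga13 (at least 7.34-fold), the oxysterol hydroxylase Cyp39a1 (at least 6.65-fold), the ubiquitin ligase Nedd4 (6.64-fold), the metallothionein Mt2 (6.37-fold), Mfhas1 (5.95-fold) and the GTPase activator Rap1gap (5.75-fold). The 3 probe sets of Nedd4 ran from 1.16 to 2.73 on the log2 scale. Folds written "at least" depend on the floor. Across the alternatives the lowest log2 ratios were 2.20 for Cd9, 2.17 for Myof, 1.05 for Ffar2 and 1.02 for Tsga13.

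The genes highest in follicular over marginal zone B cells were led by the sort gate gene Fcer2a. After it came Bach2, a transcriptional repressor of plasma cell differentiation, at 528.2 and 67.0, 7.88-fold higher in follicular cells. Il4ra, the interleukin-4 receptor alpha chain, was 5.49-fold higher, and its 3 probe sets ran from -2.46 to -0.69 as log2 marginal zone over follicular. Sox4, a transcription factor of early B cells, was at least 4.77-fold higher, and Abca1, a cholesterol efflux pump, was at 739.6 and 165.6, 4.47-fold higher, with its other probe set at -0.66 on the log2 scale. Rflnb was at least 6.68-fold, Myadm 6.43-fold and Tmem63a at least 5.81-fold higher. The other probe set of Myadm was at -1.11 on the log2 scale. Sdc1, which encodes the plasma cell antigen CD138, was at least 5.39-fold higher, but its 3 probe sets ran from -2.43 to -0.32 and the signal was only 68.3 in follicular cells. The zinc-finger gene Cxxc5 (5.27-fold), Fbxl14 (4.89-fold), the kinases Plk2 (4.87-fold) and Sbk1 (4.75-fold), Cables1 (at least 4.68-fold) and the phosphodiesterase Pde2a (at least 4.62-fold) completed the group.

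Genes previously reported for each population followed their population in this pair. Of 10 measured genes reported for marginal zone B cells, 8 were at least 2-fold higher there and 0 at least 2-fold higher in follicular cells. Their median log2 ratio of 2.25 lay above all 10000 random lists, whose middle 95% ran from -0.32 to 0.29. Beside the genes named above, Sema7a at 2.31-fold and the Notch target Dtx1 at 2.08-fold, both chosen after their values were seen, were past the threshold. Of 10 measured follicular genes, 5 were at least 2-fold higher in follicular cells and 0 in marginal zone cells, with a median of -1.05, below all random lists. Itgb7, an integrin chain of gut homing, was 2.68-fold and Cmah, a sialic acid hydroxylase, 2.55-fold higher in follicular cells. Klf2, chosen after its values were seen, was the fifth with Fcer2a, Il4ra, Itgb7 and Cmah. Each list holds a sort gate gene; without it the medians were 2.82 and -0.80, at percentiles 100 and 0.08. Macrophage markers were also higher in the marginal zone sample, with a list median of 0.53. Of the 10 marginal zone genes, 7 were set aside as also expressed by macrophages. The 3 kept were Cd1d1 and Dtx1, with the values above, and the sort gate gene Cr2. The log2 ratio of Cr2, 1.68, was also their median. No macrophage sample was measured, so macrophage expression of these 3 was not checked and their median cannot exclude macrophage RNA. This alternative was chosen after seeing the data.

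**Figure D2:**
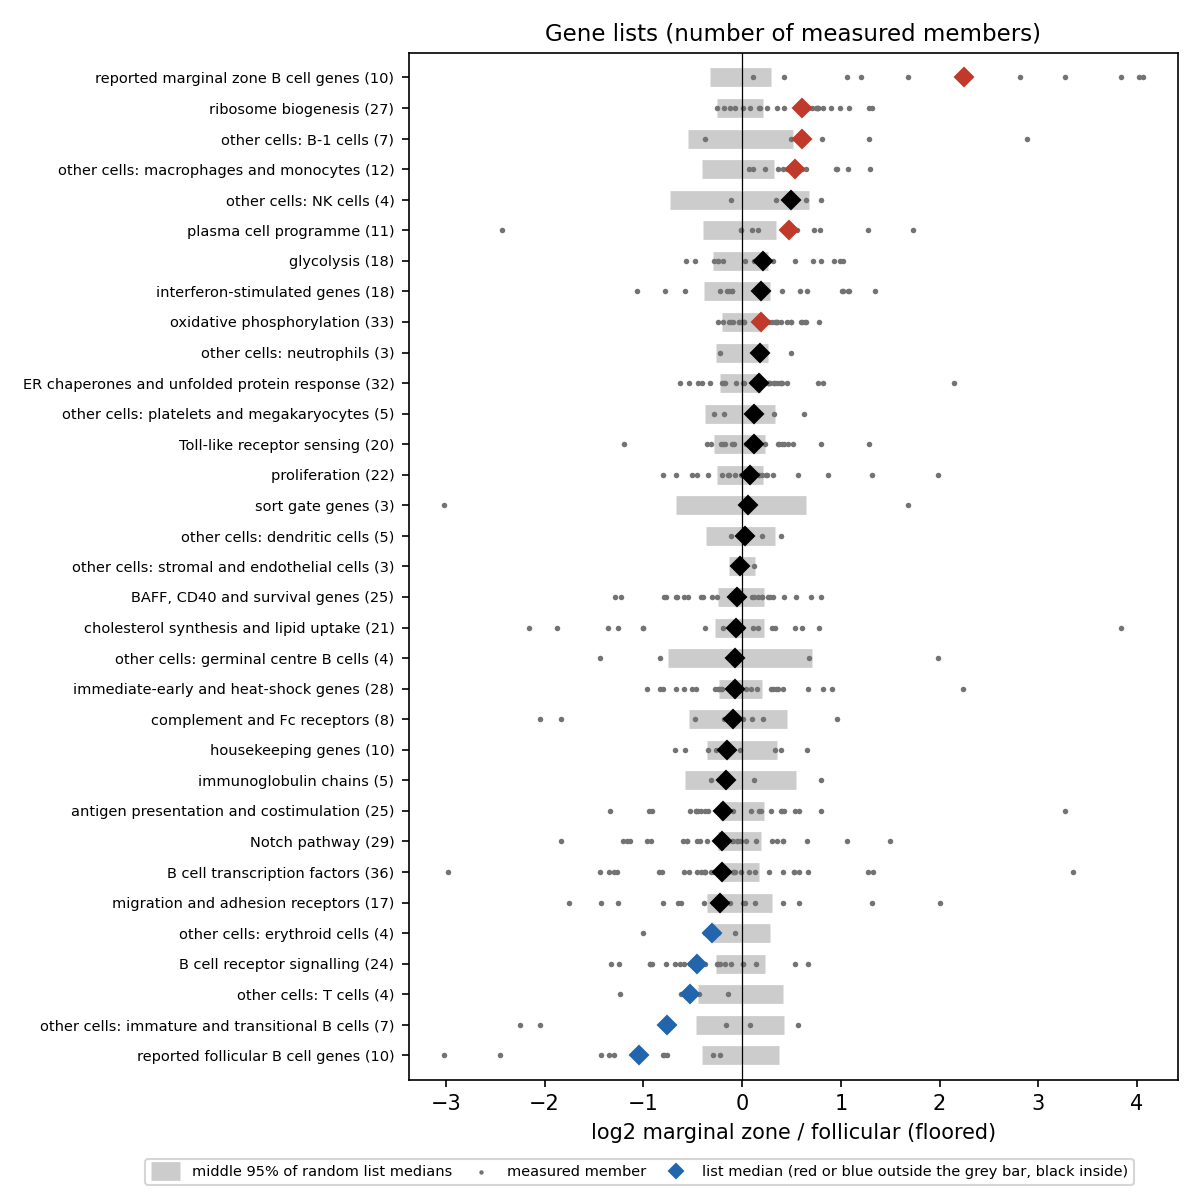
Log2 ratio of marginal zone over follicular signal (horizontal axis) for the 33 preset gene lists, with the number of measured members in brackets. Small grey points are member genes, grey bars the middle 95% of medians of 10000 matched random lists, and diamonds the list medians; 6 medians lie above their bar (red) and 5 below (blue).

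Of the 33 lists, 6 had medians above and 5 below the middle 95% of their random lists, and 22 lay inside. Ribosome biogenesis genes had a median of 0.61 over 27 members, above all random lists; 23 members had the higher signal in marginal zone cells, although only 3 reached 2-fold. Nop16 was at least 2.49-fold, Polr1b, a subunit of RNA polymerase I, at least 2.44-fold, Rrp1b 2.12-fold and Nle1 1.99-fold higher. Oxidative phosphorylation genes had a small but shared difference, with a median of 0.19 at percentile 97.9; 25 of 33 were higher in marginal zone cells and 0 reached 2-fold. Atp5b was 1.72-fold, Ndufb5 1.57-fold, Sdhd 1.56-fold and Uqcrq 1.52-fold higher. The oxidative phosphorylation call ended with a pseudocount in place of the floor (percentile 97.3). Glycolysis genes lay inside the random range, with a median of 0.21 over 18 members. Tpi1 (2.03-fold), Hk2 (1.99-fold), Pgk1 (1.91-fold) and Pgam1 (1.73-fold) were nevertheless higher in marginal zone cells. The log2 ratio of Hk2 fell to 0.17 under an alternative.

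Plasma cell genes had a median of 0.47 over 11 members, at percentile 99.2, with 2 members at least 2-fold higher in marginal zone and 1 in follicular cells. Prdm1, the master regulator of plasma cells, was at 12.7 and 30.9 and 2.43-fold higher in marginal zone cells, Il10 at least 3.33-fold and Slamf7 1.72-fold; Sdc1 was the member that went the other way. The signals of Il10 were 2.9 and 42.2. The call of the plasma cell list ended under 5 of 11 alternatives, the lowest percentile being 83.2 with no floor. Over the other probe sets of 3 of its genes the median was only 0.12. The 32 endoplasmic reticulum chaperones and unfolded protein response genes lay inside the range, with a median of 0.17 and 31 members within 2-fold. Pdia4, a disulfide isomerase, was at least 4.42-fold higher in marginal zone cells, at 1.4 and 56.0. Sel1l was 1.76-fold and Edem1 1.70-fold higher there, and Creld2 1.55-fold higher in follicular cells.

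B cell receptor signalling genes had lower signals in marginal zone cells, with a median of -0.46 over 24 members, at percentile 0.05. Of these, 19 were lower there, 2 of them at least 2-fold. Genes of phosphoinositide 3-kinase led, with Pik3r1 at 31.7 and 10.6, the latter under the floor, and Pik3cd 2.38-fold higher in follicular cells. The kinase Syk was 1.92-fold and Cd79b, a signalling chain of the receptor, 1.90-fold higher in follicular cells, at 740.7 and 386.7 and at 1040 and 545.9. Over the other probe sets of 11 of these genes the median was -0.29.

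Transcription factors of B cells went both ways, with 3 at least 2-fold higher in marginal zone and 5 in follicular cells of 36 measured, and a median of -0.20 at percentile 3.01. Beside Id2 and Bach2, Bcl6, the germinal centre repressor, was 2.70-fold higher in follicular cells. Runx1 was 2.55-fold higher in follicular cells by its brightest probe set, but its 4 probe sets ran from -1.35 to 1.42 and their mean was 0.036. Myc, at 78.6 and 196.8, was past 2-fold in marginal zone cells, as was Prdm1, and Irf8 (2.41-fold) and Klf2 (2.46-fold) were higher in follicular cells; Myc, Irf8 and Klf2 were chosen after their values were seen. The list lay below the random range under 6 of 11 alternatives.

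The Notch pathway list lay inside the random range, with a median of -0.20 over 29 members. Hes5, a Notch target, was 2.82-fold higher in marginal zone cells, at 13.8 and 39.1. Dll1, a Notch ligand, was at least 3.57-fold higher in follicular cells. The transcriptional repressor Spen, at 33.2 and 14.4, and the gamma-secretase subunit Aph1a, at 2.25-fold, were also past 2-fold in follicular cells. Dtx1 in marginal zone cells and Lfng in follicular cells (at least 2.20-fold), both chosen after their values were seen, complete the 2 and 4 members past 2-fold. The receptor gene Notch2, chosen after its values were seen, was at 816.6 and 418.3 by its brighter probe set, 1.95-fold higher in follicular cells. Its other probe set was at -0.36 on the log2 scale.

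Migration and adhesion receptors lay inside the random range as a list, at a median of -0.23 over 17 members, and their members diverged. Itgb1, the beta-1 integrin chain, was at least 4.00-fold higher in marginal zone cells by its brighter probe set and at 0.65 on the log2 scale by the other; with the floor at the 75th percentile its log2 ratio was 0.15. The hyaluronan receptor Cd44 was 2.49-fold higher there. Cnr2, a cannabinoid receptor, was 3.36-fold higher in follicular cells, beside Itgb7 and S1pr4 (2.39-fold), a sphingosine-1-phosphate receptor chosen after its values were seen. Complement and Fc receptors had a median of -0.09 over 8 members. Cd55, an inhibitor of complement on the cell surface, was at 188.3 and 52.7, 3.58-fold higher in follicular cells, and Cd93 was at least 4.14-fold higher there. Cd46 was at least 1.95-fold higher in marginal zone cells, and Fcrla 1.39-fold higher in follicular cells.

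Toll-like receptor genes lay inside the range, with a median of 0.12 over 20 members. Ly96, the partner of Tlr4, was 2.44-fold, Unc93b1, which delivers endosomal Toll-like receptors, 1.74-fold and Ly86 1.43-fold higher in marginal zone cells, while the adaptor Tirap was 2.28-fold higher in follicular cells. This list lay above the range under 3 of 11 alternatives. Antigen presentation genes had a median of -0.19 over 25 members; beside Cd1d1, the class II transactivator Ciita was at least 2.53-fold, Cd83 1.92-fold and Icosl 1.88-fold higher in follicular cells. Survival genes of the BAFF and CD40 pathways had a median of -0.05 over 25 members. Traf5 was 2.45-fold, Birc3 2.34-fold and Birc2 1.73-fold higher in follicular cells, and Cd40 1.74-fold higher in marginal zone cells. Immunoglobulin chains had a median of -0.16 over 5 members, all within 2-fold, with Ighm at 3673 and 2958. Its 4 probe sets went both ways, from -0.31 to 0.18. Igk was 1.17-fold and Ighg3 at least 1.12-fold higher in follicular cells, and Iglv1 at least 1.74-fold higher in marginal zone cells. These genes share sequence, so their probe sets may not be told apart.

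Cholesterol and lipid genes split: of 21 measured, 6 were at least 2-fold higher in follicular cells and only Cd36 in marginal zone cells, with a median of -0.06. The follicular members were the efflux pumps Abca1 and Abcg1 (3.67-fold) and, of the synthesis pathway, Msmo1 (at least 2.56-fold), with Sc5d (2.39-fold), Fdft1 (2.01-fold) and Sqle (75.5 and 37.7) chosen after their values were seen. Interferon-stimulated genes had 5 members at least 2-fold higher in marginal zone and 1 in follicular cells of 18, with a median of 0.19 inside the range. Oas1a was 2.54-fold, Rsad2 2.12-fold and Oasl1 2.10-fold higher in marginal zone cells, and Rtp4 2.09-fold higher in follicular cells. Mx1 and Oas2, both at least 2.02-fold higher in marginal zone cells, were chosen after their values were seen. Proliferation genes had a median of 0.08 over 22 members; Mki67 was at least 3.95-fold and Ccna2 at least 2.49-fold higher in marginal zone cells, at signals of only 50.1 and 31.6 there, and Mcm6 was 1.83-fold higher in marginal zone cells. Cenpa was 1.75-fold higher in follicular cells. Immediate-early and heat-shock genes had a median of -0.07 over 28 members. Atf3, a stress-induced transcription factor, was the one member past 2-fold, 4.70-fold higher in marginal zone cells. Hspa1b was 1.88-fold higher there, and Junb 1.94-fold and Btg2 1.78-fold higher in follicular cells. The 10 housekeeping genes had a median of -0.16 and were all within 2-fold. Tbp, at 1.60-fold higher in follicular, and Rplp0, at 1.57-fold higher in marginal zone cells, differed most. Gusb (at least 1.49-fold higher in follicular cells) and Ywhaz (1.32-fold higher in marginal zone cells) followed. The 7 probe sets of Ywhaz ran from -0.64 to 0.63 on the log2 scale. Its log2 ratio turned to -0.18 under an alternative.

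Markers of other cell types were mostly near the floor. Macrophage and monocyte genes had a median of 0.53 over 12 measured members, at percentile 99.96, and all 12 were higher in the marginal zone sample. Csf1r was at 17.3 and 42.5, Lyz2 at 12.9 and 25.2, Cd5l at 11.1 and 26.7 and C1qb at 2.9 and 24.5. B-1 cell genes had a median of 0.61 over 7 members, at percentile 99.6, led by Cd300lf and Ptpn22 (2.43-fold higher in marginal zone cells), with Ctla4 at 22.2 and Arid3a at 21.9 there; this call ended under 3 of 10 alternatives (lowest percentile 97.1). Immature and transitional B cell genes were lower in the marginal zone sample, at a median of -0.76 over 7 members. Of these, 5 were lower there, led by Sox4 and Cd93. Myb was 1.73-fold and Vpreb3 1.69-fold higher in follicular cells. The log2 ratio of Myb shrank to -0.11 under an alternative. Against the median, Cd24a, the brightest member at 1502 and 2225, was higher in marginal zone cells by all 3 of its probe sets, from 0.53 to 0.66 on the log2 scale, and Igll1 was at 0.083; both were chosen after their values were seen. The immature list's call ended under 4 of 11 alternatives, with a median of -0.02 when all 13 members on the array were used with no floor. T cell genes had a median of -0.53 over 4 measured members (Zap70 at 47.2 and 19.99, Bcl11b at 19.4 and 9.996, Cd3e at 17.2 and 1.3, Cd4 at 13.9 and 2.0), and with no floor the median over 14 members was -0.03. The T cell call ended under 3 of 10 alternatives. Erythroid genes had a median of -0.31 over 4 members, all under 26 in signal (Car2 at 25.4 and 1.7, Klf1 at 16.5 and 6.0, Hba-a1 at 14.96 and 5.1, Rhag at 13.34 and 5.9), and their call ended under 6 of 10 alternatives.

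The 6 remaining lists of other cells lay inside their random ranges. NK cell genes had a median of 0.50 over 4 members, with Prf1 at 21.1 and 36.8, Ccl5 at 6.0 and 19.8, Gzma at 16.3 and 20.7 and Eomes at 18.1 and 16.7. Neutrophil genes had a median of 0.18 over 3 members, with Ngp at 11.8 and 17.9, S100a9 at 14.8 and 0.79 and Elane at 8.9 and 14.4. Dendritic cell genes had a median of 0.03 over 5, with Cox6a2 at 6.1 and 16.6, Itgax at 12.1 and 14.5, Pacsin1 at 19.7 and 18.2 and Zbtb46 at 0.91 and 12.97. Platelet genes had a median of 0.12 over 5, with Treml1 at 3.0 and 19.5, Itga2b at 16.3 and 20.4, Itgb3 at 15.5 and 7.2 and Gp1bb at 14.3 and 2.5. Stromal genes had a median of -0.02 over 3, with Col1a1 at 0.51 and 13.8, Cxcl13 at 19.2 and 18.3 and Cdh5 at 12.8 and 1.9; the sign of this median turned with median or lowess centring, as did Cdh5 with the former and Cxcl13 with the latter. Germinal centre genes had a median of -0.07 over 4, where Mki67 and Bcl6 went opposite ways. Basp1 was 1.77-fold higher in follicular and Efnb1 at least 1.60-fold higher in marginal zone cells. The other probe set of Efnb1 was at -0.19 on the log2 scale, so its direction is not settled.

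Other genes named at 2-fold or more had a probe set short of it, here with its log2 ratio. In marginal zone cells these were Rrp1b (0.69), Rsad2 (0.38), Ccna2 (0.20), Csf1r (0.17) and Tpi1 (0.92). In follicular cells they were Sox4 (-0.89), Irf8 (-0.77), Cmah (-0.66), Birc3 (-0.63), Fdft1 (-0.60), Bcl6 (-0.38), Aph1a (-0.31) and Sc5d (-0.17).

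A named gene with no signal above a raised floor, such as Il10, Dll1, Polr1b or Hes5, was not run under that floor. Of the 72 named genes past 2-fold, 41 fell short of it under at least 1 alternative run on them. With the floor at the 75th percentile, which raises the dimmer signal, 21 did. In marginal zone cells these were Mki67 (0.13 on the log2 scale), Itgb1, Oasl1 (0.22), Oas1a (0.25), Pdia4 (0.29), Rrp1b, Cyp39a1 (0.88) and Rap1gap (0.91). In follicular cells they were Zap70 (-0.045), Cd93 (-0.20), Pde2a (-0.36), Cables1 (-0.38), Sox4 (-0.40), Traf5 (-0.55), Tirap (-0.56), Sdc1 (-0.58), Itgb7 (-0.68), Tmem63a (-0.69), Pik3cd, Fbxl14 (-0.77) and Rflnb (-0.89). With a pseudocount 21 did, namely Cmah, Hes5, Spen, Pik3r1, Pik3cd, Ly96, Tirap, Prdm1, Traf5, Ciita, Nop16, Rrp1b, Tpi1, Msmo1, Oas1a, Rsad2, Oasl1, Rtp4, Zap70, Csf1r and Cd5l. With the mean of all probe sets 7 did, namely Aph1a, Bcl6, Runx1, Birc3, Ccna2, Rrp1b and Rsad2. Car2 did under all 4 other scalings, Tpi1 with fewer kinds of probe sets, and Itgb1 with the lower floor and with none.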

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

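The counts of this part were chosen after the data were seen. Some probe sets with no gene in the annotation used here also differed. Of 293 such probe sets with a signal of at least 45.7 on one array, 12 were at least 2-fold higher in marginal zone and 11 at least 2-fold higher in follicular B cells. Of 306 equally bright probe sets annotated to several genes, 13 and 7 were. Neither class of probe sets enters a comparison of named genes. Of 3898 equally bright genes, each by 1 probe set, 207 and 229 were past 2-fold, 11.2% in all, so neither class showed an excess. No group held enough arrays for a test of outlying samples, and no contrast was measured in more than 1 setting.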

How the results depend on the processing

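The counts without genes of other cells, the shortened marginal zone list and the medians over other probe sets were tests chosen only after the results were seen. No paired analysis was possible because there was 1 array per population. Both are labelled replicate 1, and the labels do not say whether they came from the same mice. The 4 scaling alternatives planned for array controls were not run, since no control probe sets were analysed here. The number of genes past 2-fold followed the floor: 1277 were higher in marginal zone and 1389 in follicular cells with the floor at the 25th percentile, 1988 and 2086 with no floor, and 125 and 143 with the floor at the 75th percentile. With a pseudocount they were 259 and 308, of which 181 and 210 were among the 338 and 374, so many genes past 2-fold depend on how low values are treated. The thresholds of 1.5-fold and 3-fold gave 1047 and 1218, and 66 and 67 genes. Scaling and probe set rules gave 296 to 385 genes higher in marginal zone and 325 to 365 in follicular cells. Marginal zone genes made up 47.5% of the genes past 2-fold in the chosen setting and 53.7% after lowess centring. Without any gene of the other-cell lists the counts were 333 and 369. Lists above the random range numbered 3 with the floor at the 75th percentile, and lists below it 3 with the floor at the 25th percentile and 3 with a pseudocount, against 6 and 5. The lists of reported genes, ribosome biogenesis, B cell receptor signalling and macrophage markers kept their side of the range under every alternative for which a random range was computed, which leaves out the medians over other probe sets. Lists that lay outside the range only under an alternative were Notch, germinal centre, endoplasmic reticulum, glycolysis, interferon, migration and survival genes, each under 1 alternative, Toll-like receptor genes under 3 and transcription factors under 6; the cause was not tested. The correlation of the arrays was 0.914, 0.925 and 0.865 with the floor at the 25th percentile, at the 75th percentile and absent. The SD between probe sets of 1 gene was 0.763 and 0.304 with the lower and higher floor. Of 72 named genes past 2-fold, 71 kept their direction under all alternatives run on them and 31 stayed past 2-fold in all of those. A gene with no usable probe set under an alternative was not run under it. With the floor at the 75th percentile this left out Il10, Dll1 and Polr1b, which count among the 31. Runx1 reversed, to 0.036, when the probe sets of a gene were averaged, since they disagree. Signals near the floor set the limit: 99 of the 338 genes and 98 of the 374 were below it on the other array. Their folds depend on where the floor is set.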

Other observations

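The 6 gene lists of this part, the cycling-cell test, the abundant-transcript test and the medians over other probe sets were tests chosen only after the results were seen; lowess centring was planned as a scaling, and its use as a test of 2 lists was chosen afterwards. The genes named here were also chosen after their values were seen. Some genes of aminoacyl-tRNA and polyamine synthesis were past 2-fold in marginal zone B cells. Odc1, the first enzyme of polyamine synthesis, was at 742.7 and 2240, 3.02-fold higher, Srm 3.51-fold, Farsa 3.28-fold and Rars 2.06-fold. Of 20 measured aminoacyl-tRNA synthetases and polyamine genes, 18 were higher in marginal zone cells. In a list of lysosomal and related genes, 7 of 36 were at least 2-fold higher in marginal zone and 0 in follicular cells. These were Cln8 at 4.70-fold, Grn at 3.90-fold, Pld4 at 3.67-fold, Ctsz at 3.57-fold, Psap, the saposin precursor, at 2.74-fold, the protease Ctsb at 2.43-fold and Gaa at 2.33-fold. A probe set of Cln8 (0.52), of Psap (0.77) and of Ctsb (0.64) was short of 2-fold on the log2 scale. Of 32 DNA repair genes, 4 were at least 2-fold higher in follicular cells, namely Fen1 (3.72-fold), Nbn (3.48-fold), Msh6 (3.32-fold) and Parp1 (2.63-fold).

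The higher ribosome biogenesis genes may be part of a broader biosynthetic difference: 19 synthetase and polyamine genes, without Srm, had a median of 0.34 at percentile 99.6, although 35 cytosolic ribosomal protein genes, without Rplp0 and Rpl13a, had one of 0.087 at percentile 70.1, with Rpl41 alone past 2-fold (2.37-fold, but 0.16 on the log2 scale by its lowest probe set). A fault of single probe sets is argued against by the other probe sets of 14 genes, with a median of 0.74 (bootstrap interval over genes 0.31 to 0.93) and 12 of 14 higher in marginal zone cells. Lowess centring, which takes out a smooth signal-dependent difference between the arrays, left the median at 0.61. The random lists were already matched on signal, so staying outside their range after this centring was no separate test. Cycling cells in the marginal zone sort stay open, since proliferation genes went both ways: Mki67, Ccna2 and Mcm6 were higher there and Cenpa, Mcm2, Mcm3 and Mcm5 lower (-0.80, -0.46, -0.50 and -0.67), the list's upper quartile was 0.25, 13 of 22 genes had signals under 45.7 on both arrays, and the 9 brighter ones had a median of -0.14 and an upper quartile of 0.11. A difference in labelling between the arrays, or between the mice, stays open, since each population has 1 array.

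The lower median of B cell receptor signalling genes in marginal zone cells was not removed by lowess centring, which left -0.43 at percentile 0.12. The random lists were already matched on signal, so this percentile is no separate test of a signal-dependent difference. A fault of single probe sets stays open: the other probe sets of 11 genes had a median of -0.29, with 7 lower in marginal zone cells and a bootstrap interval from -0.71 to 0.09. The population is the biological explanation that the design offers, and 1 array each cannot separate it from the sort or the labelling.

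Macrophage RNA in the marginal zone sample is a candidate source of the higher macrophage markers. Of 21 list members with a probe set, 14 had the higher unfloored signal there, where an even split would give 10.5. These were all 12 measured members but only 2 of the 9 others. The 12 were already known to be higher and exceed 10.5 alone, so the count adds no support. The B220 beads and the CD21 and CD23 gate were used to select B cells, but how many macrophages remained was not measured here. Whether macrophage RNA also brought the higher signals of Cd36, Cd9, Lgals3, Grn and Ctsz stays open. The signal in marginal zone minus follicular cells had a median of 229 over these 5 genes and of 9.16, at most 21.6, over Lyz2, C1qa, C1qb and C1qc, but 2 of the latter were under the floor on both arrays and signals of different probe sets have no common scale. Expression of macrophage genes by marginal zone B cells themselves was not tested.

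FOXO target genes may be lower together in marginal zone B cells: 12 targets, without 9 that had been seen or listed before, had a median of -0.57 at percentile 0.14 of random lists. Among them Bnip3 (2.95-fold) and Irs2 (2.35-fold) were at least 2-fold higher in follicular cells and Gadd45a (2.13-fold) in marginal zone cells. The high follicular signals of Abca1, by 1 of its 2 probe sets, Abcg1 and Mylip (3.55-fold) raised the hypothesis that targets of the sterol sensor LXR are lower in marginal zone cells. Without these and Apoe, 12 targets had a median of 0.26 at percentile 97.7, on the opposite side. The list of lysosomal and related genes without Ctsz, Grn, Pld4 and Cln8 had a median of 0.077 over 32 genes, at percentile 81.9, inside the random range. DNA repair genes without Msh6, Nbn and Fen1 had one of -0.049 over 29 genes, at percentile 47.5, also inside.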
